A study of Homo sapiens with 9 samples.

How the data were processed

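RNA was profiled in HEK293T cells, a human embryonic kidney line, that had been transfected with the pRK5 vector carrying wild-type BPIFB4 (WT-BPIFB4), with the same vector carrying the longevity-associated variant (LAV-BPIFB4), or with an empty plasmid. Per the labels, transfection was in triplicate with a lipid reagent, the cells were serum-starved for 18 hours from 24 hours after transfection, total RNA was extracted with a column kit that retains small RNA, and Cy3-labelled cRNA was made with an Illumina amplification kit. Each of the 9 samples has 1 array, with 3 arrays per group. The array identifiers place all 9 on 1 chip, with each group in adjacent positions, so the group and the place on the chip cannot be told apart. The labels do not say whether the triplicates are separate cultures or separate transfections, so p-values measure the spread between these samples.

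The deposited files hold 2 kinds of values. The deposited non-normalized table gives, per the file headers, a probe intensity and a detection p-value for each array. The authors made both with BeadStudio, whose version is not given. The detection p-value compares a probe with the negative controls of its own array, and on each array it fell with the signal of that array. The deposited value table gives a second intensity per sample, on a linear scale, for which the labels do not state the normalization. For the 6 empty vector and WT-BPIFB4 samples that second intensity was a linear function of the non-normalized signal of the same array. For the 3 LAV-BPIFB4 samples it matched none of the 9 non-normalized arrays. The comparisons therefore use the non-normalized table, and statements on LAV-BPIFB4 refer to the arrays that the labels name for that group. Excepted are the alternatives and comparisons that use the value table. These alternatives enter the ranges and counts given over the alternatives. For LAV-BPIFB4, such ranges and counts therefore reflect a change of values as well as of processing.

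Signals were background-corrected, given an offset of 16, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with the background estimated from the detection p-values. Of 47310 probes, 20914 with a detection p-value under 0.05 on at least 3 arrays were kept. Gene symbols came from the array's gene table, 30066 probes having a current symbol through their gene identifier in the RefSeq annotation of GRCh38.p14, which was used for names and gene types only. Of the kept probes, 15778 carried 1 gene symbol, for 11830 genes, and 5136 (24.6%) carried none or several. A gene was represented by its kept probe with the highest mean over the 9 arrays.

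One linear model with 3 group means was fitted to the 9 arrays with lmFit, followed by eBayes with an intensity trend. Each of the 3 pairs of groups was compared, two-sided, and an F-test covered all 3 groups. Probes with a Benjamini-Hochberg adjusted p under 0.05 over the kept probes were called. Group levels are given as mean ± SD of log2 intensity over 3 arrays, and log2 changes with the standard error of the fit. For arrays, only their number limits the precision that can be stated.

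The 24 gene lists (688 members) and 6 marker lists (57 members) were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. Of the members, 569 and 21 were measured. Lists with at least 3 measured members, 23 gene lists and 3 marker lists, were tested against the other genes with limma camera at a preset correlation of 0.01, adjusted over the lists of a family in a comparison. An estimated correlation and limma fry, which tests whether the members of a list move on balance in one direction, were alternatives. Named were the 10 genes with the highest and the 10 with the lowest called change whose groups did not overlap, and up to 4 called members of each list. Where nothing was called, the 5 genes with the smallest p in each direction were named, as values. The 2 log2 changes against the empty vector share the same 3 control arrays, so their correlation and the overlap of their calls were set beside 100 simulated sets each in which nothing changed.

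The pipeline was tested on simulated data with the same 20914 probes, in which 67 probes were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. For WT-BPIFB4 against the empty vector it recovered 25.4%, 70.1% and 100% of them, with 5.11% of the calls false. For LAV-BPIFB4 against the empty vector it recovered 19.4%, 68.7% and 100%, with 9.42% false. For LAV-BPIFB4 against WT-BPIFB4 it recovered 31.3%, 70.1% and 100%, with 4.96% false. A gene list, that of mitosis, shifted by 0.3 on the log2 scale was called in 50 of 50 simulated sets in each comparison. Genes varied independently in these sets, so they do not test lists whose members vary together.

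Alternatives covered the background correction, the offset (50), median scaling, the value table, the probe filter, the variance model, array weights, the replicate number as a term, each array left out in turn, a fit of only the 2 groups compared, a fold threshold of 1.5, 1 probe per gene and the list tests. The value table with quantile normalization, a fit without small non-coding RNA genes, and the class of these genes with each array left out, were added after the data had been seen. No coordinates are given.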

Results

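The data are bead array profiles of HEK293T cells after transfection with an empty vector, WT-BPIFB4 or LAV-BPIFB4, with 3 arrays in each of the 3 groups. BPIFB4 belongs to the BPI fold family of secreted lipid-binding proteins. The series concerns a longevity-associated protein in endothelial function and vessel growth, and the arrays ask which transcripts differ in cells that over-express its wild-type or its variant form. The median signal per array ranged from 93.1 to 139, and 18940 to 20658 probes per array were detected above background. Arrays of 1 group correlated at 0.980 to 0.985 for the empty vector, 0.976 to 0.984 for WT-BPIFB4 and 0.983 to 0.987 for LAV-BPIFB4, across probes, which are not independent replicates. The first principal component held 31.8% of the variance. On it, the empty vector arrays lay between -32.1 and -29.8, the LAV-BPIFB4 arrays between 19.7 and 25.2, and the WT-BPIFB4 arrays at -12.3, 9.67 and 29.3. These WT-BPIFB4 values are those of replicates 1, 2 and 3, in the order of their places on the chip. The empty vector and LAV-BPIFB4 arrays did not follow such an order.

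The transgene could not be followed. The array has 1 probe for BPIFB4, which was at background on all 9 arrays (detection p-value 0.474 to 0.896, 0 arrays detected). Its mean signal was 93.7 ± 8.59 (SD, n = 3) with the empty vector, 98.7 ± 8.61 with WT-BPIFB4 and 99.2 ± 10.6 with LAV-BPIFB4, so no fold is given. Whether the probe lies inside the transfected sequence is not known, and it says nothing about the success of the transfections.

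Cells with WT-BPIFB4 had higher levels of heat shock transcripts than cells with the empty vector. HSPA6, a strictly stress-inducible HSP70, rose 17.9-fold, from 9.74 ± 0.49 to 13.90 ± 0.14 (log2 intensity, SD, n = 3), and HSPA7, annotated as a transcribed pseudogene of the same family, rose 19.1-fold (log2 change 3.59 to 4.49 over the alternatives). The HSP40 co-chaperone DNAJB1 rose 3.77-fold. TCEAL7, a transcription elongation factor A-like gene (limma adjusted p = 2.22e-13), PPIL2, a nuclear cyclophilin with a U-box, and the inducible HSP70 gene HSPA1A rose from levels detected on 1 of 3 empty vector arrays to levels detected on all 6 BPIFB4 arrays. Their size depends on the treatment of the background, with log2 changes of 4.84, 3.96 and 3.90 here and of 2.82 to 5.01, 2.10 to 4.15 and 2.06 to 4.14 over the alternatives, so their order is not given. HSPA6 and HSPA7 are near-identical in sequence, so their probes may not separate the copies. HSPA1A and HSPA1B are near-identical too, but their probes did not read alike. The HSPA1B probe, detected on all 9 arrays, differed by only 0.85 with WT-BPIFB4 and 0.93 with LAV-BPIFB4. PPIL2's other kept probe differed by 0.43 with WT-BPIFB4 and by -0.37 with LAV-BPIFB4.

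Also among the 10 largest rises with WT-BPIFB4 were small RNA genes, namely the minor spliceosome RNA RNU4ATAC (3.76-fold), the U1 gene RNU1-3 (3.24-fold) and the C/D box gene SNORD15B (3.46-fold), and the chromatin protein gene PWWP3A (3.21-fold). Levels of small RNA genes also varied together between replicate arrays of the same group. Among the probes that represent genes, and under the naming rule, the largest falls were in SNORA71C, an H/ACA box RNA (2.74-fold lower), the polycomb gene PHC1, ID4, an inhibitor of helix-loop-helix factors, the dynein light chain gene DYNLT3 (2.30-fold lower) and the stress-induced transcription factor gene ATF3 (2.08-fold lower). WSB2, ZNF711, the kinase gene TAOK1, ZFP1 and the histone demethylase gene KDM3A fell 2.06-fold, 2.05-fold, 1.97-fold, 1.92-fold and 1.91-fold. ZFP1's other kept probe differed by -0.59 and was not called. PHC1 and ID4 were detected on 2 and 1 of 3 WT-BPIFB4 arrays, so no fold is given for them, and their log2 changes ranged from -1.53 to -0.59 and from -1.50 to -0.45 over the alternatives, as those of RNU4ATAC and SNORD15B did from 1.06 to 2.17 and from 1.05 to 1.97.

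The list of cytosolic heat shock genes rose with WT-BPIFB4. Of 24 measured members 7 rose and none fell, 8 rose adjusted over the list alone, and the median change was 0.23 (camera adjusted p = 1.31e-06). The call was lost with an estimated correlation (adjusted p = 0.462) and held with fry (adjusted p = 0.00503). Besides HSPA6, HSPA1A and DNAJB1, the HSP70 co-chaperone gene BAG3 rose 2.17-fold. The integrated stress response list had a median change of 0.13 (camera adjusted p = 0.0223, but adjusted p = 0.806 with an estimated correlation and 0.338 with fry). Its called members did not move one way, and 6 rose and 1 fell adjusted over the list alone. PPP1R15A, which directs a phosphatase to the translation factor eIF2alpha, rose 2.25-fold and the sestrin gene SESN2 rose 1.89-fold, whereas ATF3 fell, and 31 of 34 members were not called. The mitosis list had a median change of -0.18 (camera adjusted p = 0.0181, but adjusted p = 0.796 with an estimated correlation and 0.209 with fry). Of its 28 members 1 fell, CENPE, a kinetochore motor, by 1.54-fold, and 6 fell adjusted over the list alone. Both these calls were lost without empty vector replicate 1, empty vector replicate 3 or WT-BPIFB4 replicate 2, that of the integrated stress response also without WT-BPIFB4 replicate 1 and with a detection p under 0.01 required on all 9 arrays, and that of mitosis also with median scaling and with the value table.

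The other 20 lists tested were not called with WT-BPIFB4. Within them, IER5, an immediate early gene, rose 1.64-fold, and the replication genes CDT1 and GINS3 rose 1.65-fold and 1.57-fold. The p53 target SESN1 fell 1.62-fold, and KDM3A was the single called member of the hypoxia and glycolysis list. None of the 14 measured angiogenesis genes was called (median change 0.00045, camera adjusted p = 0.844), none of the 26 genes of the ER chaperones (adjusted p = 0.961) and none of the 6 genes for 14-3-3 proteins (adjusted p = 0.844).

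**Figure D1:**
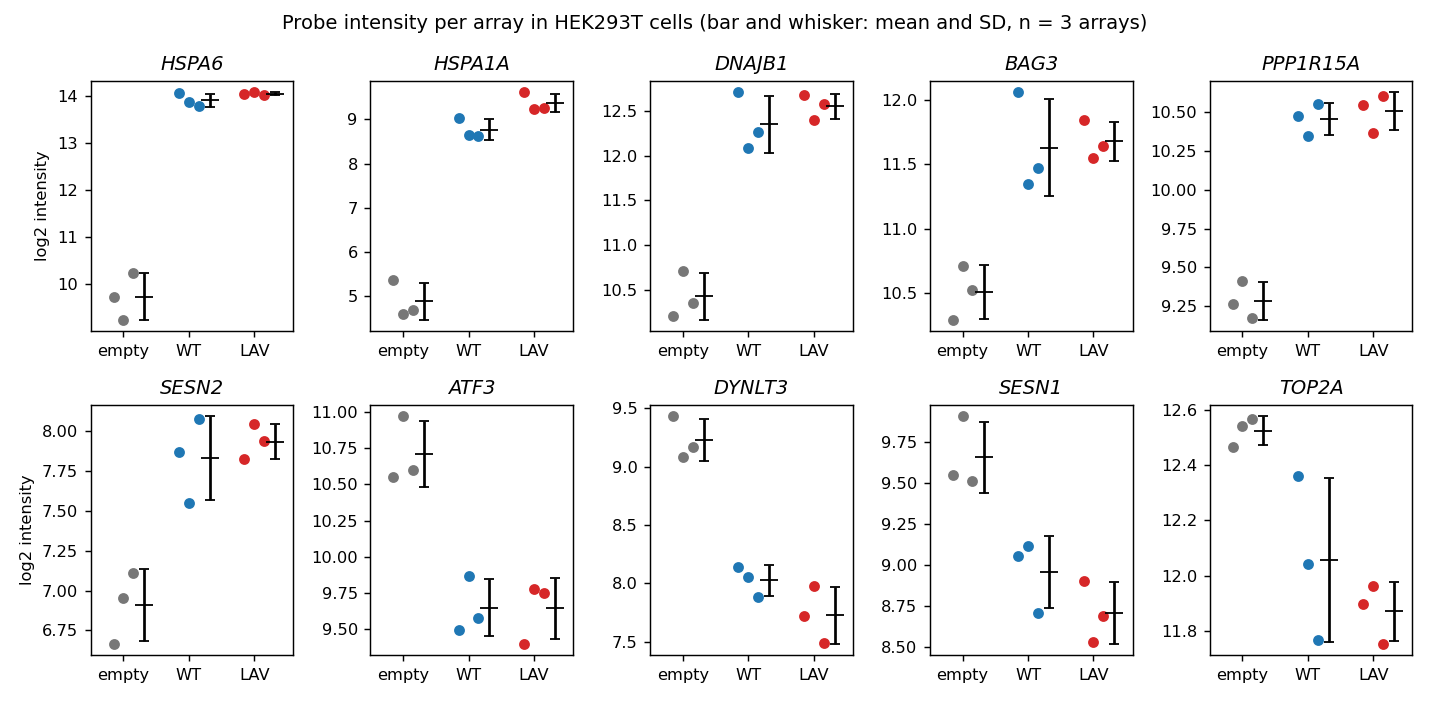
Log2 intensity of the probes of 10 named genes on each array, in 1 panel per gene with its own vertical scale. Points are arrays, and the bar with whiskers is the mean with the SD of 3 arrays of the empty vector, WT-BPIFB4 (WT) or LAV-BPIFB4 (LAV) group. HSPA6 rose from a mean of 9.74 to 13.90 with WT-BPIFB4 and 14.04 with LAV-BPIFB4, and ATF3 fell from 10.71 to 9.65 and 9.64.

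In all, limma called 224 probes for WT-BPIFB4 against the empty vector, 127 up (101 genes) and 97 down (73 genes), of which 48 and 21 changed over 2-fold. Without adjustment, 3269 probes had a p under 0.05, where chance would give 1046. The groups did not overlap for 220 of the called probes, and for 3551 of all 20914 probes, where chance gives 10%. The count depended on single arrays, being 1587 without WT-BPIFB4 replicate 1 and 67, 91, 86 and 98 without WT-BPIFB4 replicate 3, WT-BPIFB4 replicate 2, empty vector replicate 1 and empty vector replicate 3; it was 129, 135 and 117 without LAV-BPIFB4 replicates 1, 2 and 3, which share the estimate of the spread. Median scaling gave 52 (38 up, 14 down), no filter 105 (72 up, 33 down), no intensity trend 31 (27 up, 4 down), array weights 1120 (478 up, 642 down), a fit of 2 groups 87 (58 up, 29 down), and the value table gave 152 up and 51 down. Without WT-BPIFB4 replicate 1, too, more probes fell than rose (677 up, 910 down).

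TCEAL7, HSPA7, HSPA6, PPIL2, HSPA1A, DNAJB1, PPP1R15A, PWWP3A and DYNLT3 were called with WT-BPIFB4 in every alternative that kept their probe. Of the genes named in any comparison, 32 were called with WT-BPIFB4 against the empty vector. With median scaling 13 of these calls were lost, without the intensity trend 20 and with array weights 0. The call of CENPE was lost in 12 of 22 alternatives, those of ZNF711, ZFP1, KDM3A and SESN1 in 11 of 22 each and that of PHC1 in 10 of 21.

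TCEAL7, PPIL2 and the HSP70 genes were also among the 10 largest rises with LAV-BPIFB4 against the empty vector. HSPA7 rose 31.1-fold (log2 change 4.17 to 5.12 over the alternatives), HSPA6 19.7-fold (limma adjusted p = 2.31e-13) and DNAJB1 4.34-fold. TCEAL7, HSPA1A and PPIL2, again from levels detected on 1 of 3 empty vector arrays, rose by 4.65, 4.50 and 4.27 on the log2 scale, with 2.66 to 4.82, 2.56 to 4.74 and 2.36 to 4.64 over the alternatives. The small RNA genes SNORD15B, RNU4ATAC and RNVU1-7 (a U1 variant) rose 5.45-fold, 5.32-fold and 4.43-fold, and RNY5, a Y RNA, rose by 1.02 to 2.93 on the log2 scale over the alternatives, where SNORD15B and RNU4ATAC ranged from 1.56 to 2.68 and from 1.44 to 2.64. Among the 10 largest falls were PHC1, ATXN7L2 (3.27-fold lower), DYNLT3 (2.83-fold lower), the zinc finger gene ZNF184 (2.58-fold lower), MINAR1 and DEPTOR, an mTOR inhibitor (2.34-fold lower). SNORA71C, the Golgi SNARE gene GOSR1, ZFP1 and the deubiquitinase gene VCPIP1 fell 2.30-fold, 2.23-fold, 2.21-fold and 2.19-fold. RNY5 was detected on 2 of 3 empty vector arrays, and PHC1 and MINAR1 on 2 of 3 LAV-BPIFB4 arrays. The other kept probes of DEPTOR, GOSR1 and ZFP1 differed by -0.43, -0.58 and -0.60 and were not called. Ranges over the alternatives include the value table, whose LAV-BPIFB4 columns are not the labelled arrays. The order and size of these falls depend on the processing or on those columns, with log2 changes over the alternatives of -1.90 to -0.62 for PHC1, -1.98 to -0.83 for ATXN7L2, -1.47 to -0.57 for ZNF184, -1.55 to -0.41 for MINAR1, -1.48 to -0.47 for DEPTOR, -1.25 to -0.34 for GOSR1, -1.31 to -0.33 for ZFP1 and -1.24 to -0.53 for VCPIP1.

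The heat shock list rose with LAV-BPIFB4 too. Of the 24 heat shock genes 8 rose with LAV-BPIFB4 and none fell, 11 rose and 1 fell adjusted over the list alone, and the median change was 0.16 (camera adjusted p = 2.94e-04). That call was lost with an estimated correlation (adjusted p = 0.605) and held with fry (adjusted p = 0.00507), and BAG3 rose 2.25-fold. In the integrated stress response list PPP1R15A rose 2.33-fold, SESN2 2.03-fold and the pseudokinase gene TRIB3 1.55-fold, ATF3 fell 2.09-fold, and the list was not called (5 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.210). In the ER chaperone list only EDEM1, which acts in disposal of misfolded glycoproteins, was called, 1.48-fold lower.

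The mitosis and p53 target lists fell with LAV-BPIFB4. Of 28 mitosis genes 7 fell and none rose, 11 fell adjusted over the list alone, and the median change was -0.22 (camera adjusted p = 0.00932, but adjusted p = 0.688 with an estimated correlation and 0.0434 with fry). Topoisomerase gene TOP2A, the checkpoint kinase gene BUB1, the kinetochore gene NDC80 and the spindle motor gene KIF11 fell 1.57-fold, 1.54-fold, 1.54-fold and 1.51-fold. KIF11's other kept probe differed by -0.32 and was not called. With median scaling and with the value table the mitosis list was not called. Of 16 p53 targets 4 fell and none rose, 7 fell adjusted over the list alone, and the median change was -0.29 (camera adjusted p = 0.0213, but adjusted p = 0.605 with an estimated correlation and 0.0260 with fry). These were SESN1, TP53INP1 and the DNA repair gene DDB2, which fell 1.93-fold, 1.88-fold and 1.87-fold, and the cyclin gene CCNG1, which fell by 0.58 on the log2 scale. Among replication genes the polymerase gene POLA1 fell 1.70-fold, although its other kept probe differed by 0.23, while CDT1 and GINS3 rose 1.63-fold and 1.42-fold, and the list was not called (adjusted p = 0.865).

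Respiratory chain genes rose as a list. Of 50 measured, 5 rose and 1 fell, 9 rose and 3 fell adjusted over the list alone, and the median change was 0.16 (camera adjusted p = 0.0213, but adjusted p = 0.778 with an estimated correlation and 0.240 with fry). ATP5MC1, NDUFS4 and COX7C rose 1.47-fold, 1.44-fold and 1.36-fold, while the complex I gene NDUFS1 fell 1.99-fold. The call was also lost without empty vector replicate 2 and without LAV-BPIFB4 replicate 2.

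Other lists had called members with no call of the list. The ribosomal protein genes RPL8, RPL13 and RPS21 rose 1.47-fold, 1.40-fold and 1.36-fold and RPL7 fell 1.37-fold, with 5 rising and 1 falling of 67 (adjusted p = 0.386). In ribosome biogenesis PES1 rose 1.51-fold and NCL fell 1.28-fold, although with median scaling the change of NCL was 0.0011. The translation factor gene EIF6 rose 1.46-fold, and EIF4G2 and PABPC1 fell 1.38-fold and 1.29-fold. The proteasome genes PSMD8 and PSMB2 rose 1.39-fold and 1.34-fold. The sterol genes IDI1, INSIG1 and SQLE fell 1.70-fold, 1.55-fold and 1.34-fold, and the hypoxia genes KDM3A and BNIP3L fell 1.91-fold and 1.73-fold. The histone genes H2BC5, H2AC18 and H2BC12 rose 1.85-fold, 1.73-fold and 1.34-fold. The immediate early genes IER5 and JUN rose 2.02-fold and 1.44-fold. The interferon-stimulated gene ISG20, the autophagy gene ATG5 and the transferrin receptor gene TFRC fell 1.71-fold, 1.75-fold and 1.72-fold, and the lysosomal gene LAMP1 rose 1.34-fold. Other kept probes were called in the same direction for RPL13, PABPC1 (-0.86), SQLE, H2AC18 and H2BC12. They were not called for NCL, EIF6, INSIG1 (-0.25), BNIP3L (-0.23) and H2BC5. EIF4G2's other kept probes differed by -0.53 (called) and -0.30 (not called). None of the 14 angiogenesis genes was called (median change 0.0097, adjusted p = 0.865), and none of the genes for 14-3-3 proteins, NF-kappaB, NRF2 or TGF-beta targets, although adjusted over the list alone 2 of 6 genes for 14-3-3 proteins fell and 1 NRF2 target rose and 1 fell.

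**Figure D2:**
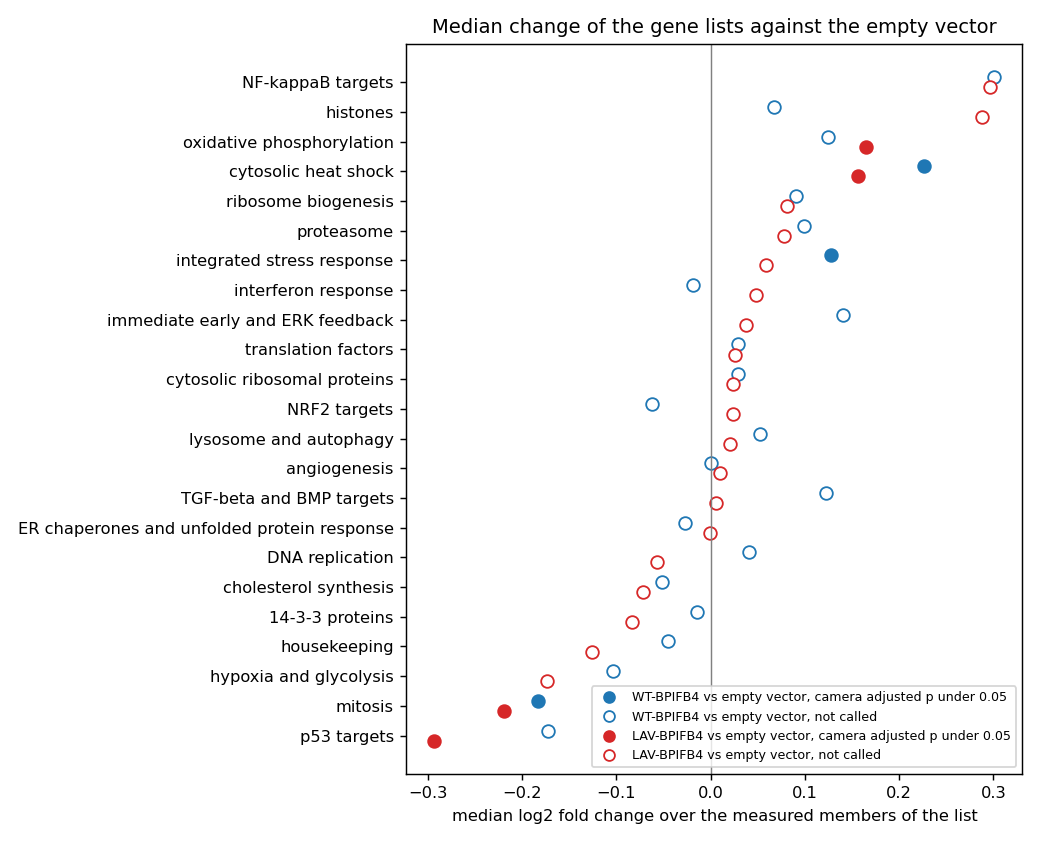
Median log2 fold change of each of the 23 tested gene lists against the empty vector, for WT-BPIFB4 (blue) and LAV-BPIFB4 (red). Filled points are lists with a camera adjusted p under 0.05 at the preset correlation, and open points are the others. The heat shock list lies at 0.23 and 0.16, the mitosis list at -0.18 and -0.22, and the p53 targets at -0.17 and -0.29, the last filled for LAV-BPIFB4 alone.

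For LAV-BPIFB4 against the empty vector limma called 1615 probes, 762 up (545 genes) and 853 down (684 genes), of which 150 and 76 changed over 2-fold. Without adjustment, 4989 probes had a p under 0.05, and 1585 of the called probes had no overlap between groups, as had 30.5% of all probes, where chance gives 10%. The count was 828, 868, 524, 823 and 495 without empty vector replicate 1, empty vector replicate 3 and LAV-BPIFB4 replicates 1, 2 and 3, and was 2544 without WT-BPIFB4 replicate 1. More probes rose than fell without empty vector replicate 1 (453 up, 375 down), empty vector replicate 3 (459 up, 409 down) or LAV-BPIFB4 replicate 2 (418 up, 405 down). Median scaling gave 243 (205 up, 38 down), the value table, whose LAV-BPIFB4 columns match none of the arrays, 996 (753 up, 243 down), no filter 923 (449 up, 474 down), no intensity trend 210 (117 up, 93 down) and array weights 2962 (1400 up, 1562 down). The F-test over the 3 groups called 821 probes, with 3990 at an unadjusted p under 0.05.

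The genes HSPA7, TCEAL7, HSPA1A, HSPA6, PPIL2 and DNAJB1, the small RNA genes RNY5, SNORD15B, RNU4ATAC and RNVU1-7, and PHC1, ATXN7L2, DYNLT3, PPP1R15A, BAG3 and IER5 were called with LAV-BPIFB4 in every alternative that kept their probe. Of the genes named in any comparison, 75 were called with LAV-BPIFB4 against the empty vector. With median scaling 46 of these calls were lost and 1 gene changed sign, and without the intensity trend 47 were lost. Without LAV-BPIFB4 replicate 3, LAV-BPIFB4 replicate 1 or empty vector replicate 1, respectively, 38, 35 and 28 were lost, and with array weights 0. The call of RPS21 was lost in 15 of 22 alternatives, those of RPL7 and PABPC1 in 13 and that of RPL8 in 12. Those of EDEM1 and ATG5 were lost in 11, and those of KIF11, BNIP3L, PSMD8 and H2BC12 in 10. Among these alternatives are those with the value table, whose LAV-BPIFB4 columns are not the labelled arrays.

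The changes against the empty vector overlapped between WT-BPIFB4 and LAV-BPIFB4. Of the probes up with WT-BPIFB4, 113 of 127 were also up with LAV-BPIFB4, where independent lists would share 4.63, and 89 of 97 were down in both, where independent lists would share 3.96. None was called in opposite directions. In 100 simulated sets without change that share their control arrays in the same way, at most 1 probe was called in both. Those sets called a mean of only 0.17 probes for WT-BPIFB4 and 0.19 for LAV-BPIFB4 against the controls, so few shared calls were possible. Among as many probes with the highest or lowest t as were called here, those sets shared a mean of 46.1 (33 to 61) up and 38.4 (28 to 49) down, with a mean of 0.250 in opposite directions, so the lack of opposite calls is no evidence of agreement. Across all kept probes the changes correlated at r = 0.785 (Spearman rho 0.752), against 0.483 to 0.518 in simulated sets without change. Their covariance was 0.0991 against 0.0263 in the simulated sets. Probes are not independent replicates, and the 3 empty vector arrays cannot be divided between the comparisons, so part of the overlap may come from the shared controls.

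**Figure D3:**
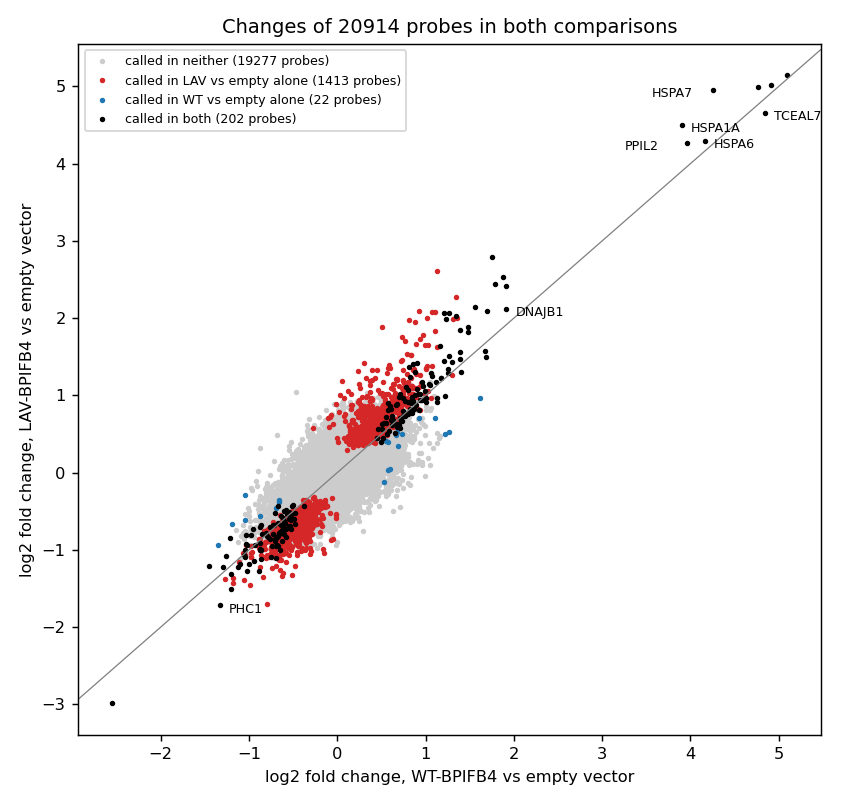
Log2 fold change of 20914 probes with WT-BPIFB4 (horizontal) and LAV-BPIFB4 (vertical) against the empty vector, with the line of equal change in grey. Black points were called in both comparisons (202 probes), red in LAV-BPIFB4 alone (1413), blue in WT-BPIFB4 alone (22) and grey in neither (19277); the comparisons share their control arrays.

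LAV-BPIFB4 and WT-BPIFB4 were compared directly to ask whether the variant differs from the wild type. Limma called 0 of 20914 probes. At an unadjusted p under 0.05 there were 976 probes, where chance gives 1046, the smallest adjusted p was 0.468, and 10.1% of probes had no overlap, where chance gives 10%. The 5 genes with the smallest p and higher values with LAV-BPIFB4 were RNA5S9, a 5S ribosomal RNA gene (1.75-fold), RPL21P28 (1.42-fold), PTGR2 (1.87-fold), RNY5 (2.80-fold) and the HSP70 co-chaperone gene BAG2 (1.74-fold). The 5 with lower values were HNRNPA3 (1.58-fold lower), the kinesin gene KIFC1 (1.56-fold lower), MYDGF (1.47-fold lower), SYDE2 and TFRC (1.41-fold lower). None of these passed the adjustment. SYDE2 was detected on 1 of 3 LAV-BPIFB4 arrays, so no fold is given for it, and PTGR2's other kept probe differed by -0.17. Against the empty vector, RPL21P28's representative probe changed by -0.29 with WT-BPIFB4 and by 0.22 with LAV-BPIFB4. Its other kept probe changed by 0.43 and 0.53, so it showed less of a difference.

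The genes among the 10 largest rises in both comparisons with the empty vector also gave no call between the variant and the wild type. HSPA6 differed by 0.14 ± 0.16 (log2, SE, adjusted p = 0.977), TCEAL7 by -0.19 ± 0.18 (adjusted p = 0.977), PPIL2 by 0.31 ± 0.29 (adjusted p = 0.976), and HSPA7 by 0.70 ± 0.22, SNORD15B by 0.65 ± 0.21, HSPA1A by 0.60 ± 0.21, RNU4ATAC by 0.50 ± 0.29 and DNAJB1 by 0.20 ± 0.15 (adjusted p = 0.972 each). For single probes, the larger number of calls with LAV-BPIFB4 is therefore not shown to be a difference between the 2 forms. As a class, chosen after the values were seen, small non-coding RNA genes were higher with LAV-BPIFB4 than with WT-BPIFB4 (154 of 176, camera adjusted p = 1.05e-20, and adjusted p = 0.0318 with an estimated correlation). Their median difference of 0.25 was 0.17 without LAV-BPIFB4 replicate 1 (134 higher, camera adjusted p = 1.24e-09), and the call with an estimated correlation was lost without empty vector replicate 3, LAV-BPIFB4 replicate 3 or any 1 of the WT-BPIFB4 arrays (adjusted p = 0.0523 to 0.105). The simulation recovered 70.1% of 2-fold and 31.3% of 1.5-fold changes in this comparison, so changes of 2-fold or less could have been missed, and larger ones in genes that vary more. Of the gene lists, p53 targets (median change -0.14) and DNA replication (median change -0.12) had the smallest camera adjusted p, 0.0640 each, and 0.766 each with an estimated correlation. None of the 23 was called, nor by fry. In 10 and 9 of 25 alternatives, respectively, these 2 lists were called, lower with LAV-BPIFB4, among them an offset of 50, no background correction and no filter, and the value table called 5 lists, all lower. The alternatives called 0 to 17 probes, 16 of those 17 higher with LAV-BPIFB4.

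No list of markers was called by camera, while fry called 2. Of the endothelial, fibroblast, blood cell and carcinoma epithelial markers, 1 of 10, 2, 3 and 2 were measured. The blood cell markers had median changes of 0.20 and 0.49 with WT-BPIFB4 and LAV-BPIFB4 (camera adjusted p = 0.132 and 0.120, fry adjusted p = 0.0899 and 0.0168), and CD68, a macrophage marker, rose 2.14-fold with LAV-BPIFB4. The 6 measured embryonic kidney and neural-like markers had median changes of -0.25 and -0.12, with 1 and 2 members falling (camera adjusted p = 0.132 and 0.167, fry adjusted p = 0.0121 and 0.00662). VIM fell with both forms, by 0.53 and 0.62 on the log2 scale, and EYA1 fell with LAV-BPIFB4 by 1.04. The 7 genes that mark RNA quality had median changes of 0.12 and 0.03 (camera adjusted p = 0.303 and 0.609, fry adjusted p = 0.473 and 0.691).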

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

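The tests of a normalized or exchanged copy were chosen after the mismatch below was seen, and the comparison of the 2 sets of LAV-BPIFB4 values was set up before its result was known.

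Signal appeared in data that the comparisons do not use. The 3 LAV-BPIFB4 columns of the deposited value table match no array of the non-normalized table, and they hold differences of their own from the empty vector arrays. After joint quantile normalization of all 12 sets of values on the log2 scale without background correction, which compresses dim probes, limma called 1357 probes between these columns and the empty vector (650 up, 707 down) and 2206 between the labelled LAV-BPIFB4 arrays and the empty vector (1012 up, 1194 down). Of these, 1107 were called in both with the same direction, where independent lists would share 71.8. The changes correlated at 0.910 across probes, against 0.483 to 0.511 in simulated sets without change that share their 3 control arrays in the same way, and their covariance was 0.0545 against 0.00743. Part of the agreement may come from these shared controls, which cannot be divided. HSPA6 rose by 4.11 in the value table columns and 4.12 on the labelled arrays (log2), HSPA7 by 4.21 and 4.38, TCEAL7 by 2.91 and 2.86, and DNAJB1 by 1.88 and 2.05, and ATF3 fell by 1.01 and 0.99. Against WT-BPIFB4, limma called 0 probes in the value table columns (1106 at an unadjusted p under 0.05) and 0 on the labelled arrays (1204).

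A normalization of the same arrays is argued against, since the rank correlation of each LAV-BPIFB4 column with the array its label names was 0.833 to 0.853, where the other 6 columns reached at least 0.999999. An exchange of columns within the series is argued against too, since the best match over all 9 arrays was 0.842 to 0.853. That the columns may come from other arrays of equally treated cells stays open, since 0 of 20914 probes differed between the 2 sets of 3 by limma (smallest adjusted p 0.99996), and so few arrays miss small changes. At an unadjusted p under 0.05 there were 453 probes, fewer than the 1046 that chance would give. Whether the 2 sets share RNA was not tested. The array identifiers of the non-normalized table end in A to F and in J to L, so it holds no arrays from positions G to I. Whether the unmatched columns come from those positions was not tested. Which set belongs to the labelled samples cannot be told apart from these files. No biological explanation was tested.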

How the results depend on the processing

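All settings were chosen before the data were examined except the value table with quantile normalization, the fit without small non-coding RNA genes and the class of these genes with each array left out. The cause of the differences below was not tested, except that testing more probes without the filter tightens the adjustment by construction. In the order WT-BPIFB4 against empty vector, LAV-BPIFB4 against empty vector, LAV-BPIFB4 against WT-BPIFB4 and all 3 groups, the counts of called probes were 224, 1615, 0 and 821. Median scaling gave 52, 243, 4 and 171, array weights 1120, 2962, 1 and 2270, and the replicate number as a term 829 (393 up, 436 down), 2740, 17 (16 up, 1 down) and 1924. Without the filter the counts against the empty vector and among 3 groups were 105, 923 and 445, and without the intensity trend 31, 210 and 56. The value table gave 996 for LAV-BPIFB4 against empty vector and 546 among 3 groups, and 911 and 522 with quantile normalization; its LAV-BPIFB4 columns are not the labelled arrays. A fit of only the 2 groups gave 87 for WT-BPIFB4 against empty vector. Leaving out 1 array gave 67 (without WT-BPIFB4 replicate 3) to 1587 (without WT-BPIFB4 replicate 1), 495 (without LAV-BPIFB4 replicate 3) to 2544 (without WT-BPIFB4 replicate 1), 0 to 0, and 248 to 2125. The last were 273 and 338 without empty vector replicates 1 and 3, 2125 without WT-BPIFB4 replicate 1, and 289, 442 and 248 without LAV-BPIFB4 replicates 1, 2 and 3. The remaining alternatives stayed within 1.5 times of these counts. The correlation of the changes (0.785) was 0.853 without background correction, 0.832 with another background method, 0.829 with an offset of 50, 0.717 without the filter, 0.864 with a strict filter and 0.833 with the quantile-normalized value table, and 0.687 to 0.808 with 1 array left out. For WT-BPIFB4 against empty vector, 3 lists were called, 5 with median scaling, 8 with the value table, 5 with array weights, 1 with fry, 0 with an estimated correlation, and 1 to 4 with 1 array left out (1 each without empty vector replicate 1 and WT-BPIFB4 replicate 2). For LAV-BPIFB4 against empty vector, 4 lists were called, 0 with an estimated correlation and 3 to 5 with 1 array left out. Between LAV-BPIFB4 and WT-BPIFB4, 0 lists were called, but 2 each (p53 targets and DNA replication, both lower) without background correction, with another background method, with an offset of 50, without the filter and with the replicate number as a term, 1 each with the strict filter, array weights and the quantile-normalized value table, 5 with the value table, and 0 to 2 with 1 array left out (2 without empty vector replicate 2, 1 each without WT-BPIFB4 replicate 1 and LAV-BPIFB4 replicate 1). Replicate numbers were not taken as pairs, since deviations from the group means correlated at only 0.0011 to 0.216 between arrays with the same number. Between arrays with different numbers they correlated at -0.150 to 0.066, and 8 of 9 arrays matched best with an array of their own number. An effect shared by arrays of the same number is therefore not excluded. Counted as reversed were values that changed sign and were called as reported or called with the new sign, while medians called in neither changed sign too. Reversed were NCL with LAV-BPIFB4 under median scaling (0.0011, adjusted p = 0.999, the adjusted p ranging from 0.0056 to 0.999 over its alternatives) and, between LAV-BPIFB4 and WT-BPIFB4, the median of the ribosomal proteins with the value table (-0.21, adjusted p = 1.09e-08). Median scaling moved the median of all probes by 0.13 between LAV-BPIFB4 and WT-BPIFB4, and no other scaling moved it by over 0.1. Probes near background limit what can be seen, as with BPIFB4 itself.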

Other observations

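The test of small non-coding RNA genes as a class, also with each array left out, and the tests of short mRNAs and of the splits between LAV-BPIFB4 and WT-BPIFB4 were chosen after the results were seen, and the bound for short mRNAs was later set for each list.

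The signal of small non-coding RNA genes, grouped by their annotated gene type, rose with both forms of BPIFB4. Whether their probes read the mature RNAs or other transcripts was not tested. Of 176 such genes 26 rose and 2 fell with WT-BPIFB4 (median change 0.40, 145 higher), and 75 rose and 2 fell with LAV-BPIFB4 (median change 0.66, 161 higher), with camera adjusted p over 7 gene types of 2.34e-17 and 4.50e-30. With an estimated correlation the adjusted p was 0.0481 and 0.0134, and with 1 array left out it ranged from 0.0116 to 0.121 and from 0.00505 to 0.0364, so for WT-BPIFB4 that call was lost without any 1 of the empty vector or WT-BPIFB4 arrays or LAV-BPIFB4 replicate 3. The 13 spliceosomal snRNA genes had median changes of 1.02 and 1.65, and 7 and 12 of them rose, although with an estimated correlation their adjusted p was 0.0601 and 0.0518. Of 151 snoRNA genes, most of which guide the modification of ribosomal RNA, 17 and 56 rose. Between LAV-BPIFB4 and WT-BPIFB4 none of the 176 genes was called by limma, but 154 were higher with LAV-BPIFB4 (median change 0.25, camera adjusted p = 1.05e-20, and 0.0318 with an estimated correlation). Without LAV-BPIFB4 replicate 1 that median was 0.17, and with 1 array left out the adjusted p with an estimated correlation ranged from 0.00907 to 0.105, over 0.05 in 5 of 9 cases. For the snRNA genes the median difference of 0.47 was 0.21 without LAV-BPIFB4 replicate 1 and 0.24 without WT-BPIFB4 replicate 1. Without these genes limma called 157 probes with WT-BPIFB4 and 1492 with LAV-BPIFB4 against the empty vector. Pseudogenes were not called as a class (adjusted p = 0.589 and 0.180), while 245 lncRNA genes had median changes of 0.06 and 0.14 (camera adjusted p = 0.0320 and 0.00484, but adjusted p = 0.262 and 0.129 with an estimated correlation), and 6 and 16 of them rose.

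For LAV-BPIFB4, background correction and normalization are argued against as the whole cause of that rise. The median change was at least 0.310 under each alternative (0.66 as reported). That lowest value was without background correction, with 161 genes higher in both settings. For WT-BPIFB4 the median went from 0.40 to 0.18 in that setting (145 higher in both). The bound of this test was set for LAV-BPIFB4 alone, so for WT-BPIFB4 the question stays open. The median shrank in both forms, so this is no contrast between them. A general shift of short transcripts cannot be told apart, since the short mRNAs moved apart by list: the 130 histone, ribosomal protein and respiratory chain mRNAs together had a median change of 0.108 with LAV-BPIFB4 (86 higher), but 13 histone genes had 0.29 (3 rose), 50 respiratory chain genes 0.16 and 67 ribosomal protein genes 0.02. The small RNA content of the extracts remains a candidate explanation. Levels of snRNA and of other small RNA genes also varied together between replicate arrays (r = 0.917, Spearman rho 0.917, exact permutation p within groups = 0.00926 for each, two-sided, 9 arrays, group means subtracted), with r = 0.916 without the 2 arrays farthest from the median. A response of the cells to BPIFB4 would give the same rise and, if it varied between arrays, the same covariation. The covariation was not set beside that of other gene classes, so it does not favour the extracts over a response. Such a response was not tested separately.

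The steep rise of the TCEAL7, PPIL2 and HSPA1A probes may reflect single probes that hybridize to another sequence. PPIL2's other kept probe moved by at most 0.425 against the empty vector, and TCEAL7 and HSPA1A have no other kept probe, so the question stays open for these genes. A second TCEAL7 probe, detected on 0 of 9 arrays, differed by 0.12 with WT-BPIFB4 and by -0.07 with LAV-BPIFB4, which goes with that explanation, but a probe at background does not settle it. A rise of the genes themselves cannot be told apart from it without the probe sequences. HSPA6's other probe rose by 4.76 with WT-BPIFB4, and HSPA1B rose by 0.85 and 0.93 with WT-BPIFB4 and LAV-BPIFB4.

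Outside the rule for named genes, and chosen after their values were seen, a probe without a gene symbol rose by 4.91 with WT-BPIFB4 and by 5.02 with LAV-BPIFB4 (log2). Another, detected on none of the empty vector arrays, rose at least 23.4-fold and 24.2-fold, counted from the lowest signal detected on those arrays or its own where higher. A second probe of TULP4, detected on 2 of 3 LAV-BPIFB4 arrays, fell by 2.55 with WT-BPIFB4 and fell by 2.99 with LAV-BPIFB4, while the probe that represents the gene differed by 0.09 and -0.12.

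Relabelling the arrays gave these counts. For WT-BPIFB4 against empty vector, fitted on 6 arrays, the real split called 87 probes and the highest other split 0, and for LAV-BPIFB4 against empty vector 2388 and 0, in both cases 1 of 10 splits. For LAV-BPIFB4 against WT-BPIFB4 the real split called 0 and the highest other 2, so all 10 splits gave as many. With 10 splits no share under 0.05 can be had. Among the 3 groups, 3 of 100 splits called at least 821 probes, the real one among them and the highest other with 1114. That share is under 0.05. Both other splits kept the 3 empty vector arrays together and mixed the BPIFB4 arrays, so the test bears on the empty vector against the rest and not on LAV-BPIFB4 against WT-BPIFB4. It cannot separate the group from the place on the chip.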
